A study of Saccharomyces cerevisiae with 78 samples.

How the data were processed

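RNA-seq libraries of 25 fusion-gene clones and 1 empty-plasmid control in yeast strain BY4742 were analysed, with 3 libraries for each of 26 groups. The series' design text speaks of 22 clones, while the sample labels hold 25, and all 25 were used. Replicates are biological replicates per the labels. The library names put replicates 1 and 2 in a first set and replicate 3 in a resubmitted set.

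The files hold counts per gene, whole numbers that the authors made and deposited without normalization. Per the labels and the series' design text, reads were trimmed and deduplicated by their molecular identifiers with fastp 0.23.1, aligned with STAR 2.5.2b, and unique hits were counted with featureCounts of Subread 1.5.2. The submitters' processing notes name genome build R64. Per the file headers and rows, however, the features lie on 212 contigs of another assembly plus 24 construct sequences, so no coordinates were taken from the files or the R64 reference, which served for gene names alone. Each file has 5231 rows, of which 5229 are genes. Of these, 5058 matched 1 R64 locus tag, 129 carry the joined locus tags of several genes (joined rows) and 42 did not match. Some genes of joined rows, such as SSA3, also have a row of their own. Some pairs, such as HSP82 and HSC82, have a joined row in each order. Which of its genes a joined row counts cannot be told from the names, so its values are given for the row. Of 6021 protein-coding genes of the reference 774 have their locus tag in no row, alone or joined. The marker genes URA3, HIS3, LEU2 and LYS2 have no row of their own. All gene features have a length divisible by 3 (coding length). A row without a name pools the construct sequences, and a row named UNDEF pools 142 features. They held a median of 0.886% and 2.36% of counts and were kept out of library sizes and tests. Of the construct sequences 23 carry clone names, and 2 clones have none. Reads of a fused gene part can match both its construct and the gene in the genome. If such reads were dropped as ambiguous, or given to 1 of the 2, the level of the gene would move, so that the level of a gene that is part of a construct is uncertain.

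Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group, and the quasi-likelihood test. All 78 libraries entered 1 fit with a term for each group and 1 for the library set, which left 51 residual degrees of freedom. The filter kept 5212 genes and left out 17. Adjusted p-values are Benjamini-Hochberg values within each comparison, with a threshold of 0.05 applied to unrounded values. The comparisons were each clone against the control, the mean of the 25 clones against the control, all groups against each other, each clone against the mean of the other groups, and the library sets. Standard errors are the log2 fold change over the root of the F statistic. CPM values are scaled by TMM. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for 42 lists and 26 contrasts together. An estimated correlation was the alternative.

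The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each clone, up to 3 leading genes past the threshold with a log2 fold change of at least 1 against the other groups and a lowest CPM above that of all 75 other libraries. For the average it takes up to 15 genes on each side, ranked by the median clone, with at least 20 of 25 clones on that side and 10 CPM. For the 4 clones with the most changed genes it takes up to 10 genes on each side, and for the others up to 2, with at least 10 CPM and no overlap of the 3 clone and 3 control values. Of a list that is described it takes up to 4 members. Some genes that the rule gives were left out for length.

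The alternatives were a replicate block in place of the library set term (324 genes for the average of the clones), no such term, RLE size factors, no filter, DESeq2 1.42.0, the first set alone, and leaving out each library in turn. Separate batches for row A and for rows B and C together of the resubmitted plate were added after the data were seen. This fit is called plate rows as separate batches below. The test was tried on simulated counts with 200 changed genes. For M490-A12 against the control, with 5211 genes, it recovered 85.1% of genes changed 1.5-fold and 100% of those changed 2-fold. Simulated libraries with no change gave 2 calls over the 25 clone comparisons. The simulated libraries were independent, with the same dispersion for all genes and the same shift between sets in all groups. They do not show the error rate where replicates lie close together in pairs or plate rows differ. Replicates 1 and 2 of a group differed by a chi-square of 2.07 to 18.1 per gene, against about 1 for sampling noise, and first-set and resubmitted libraries by 54.1 to 158, so no library was taken as a duplicate. Replicates 1 and 2 thus lay far closer together than libraries of different sets. What such a pair shared in culture or handling cannot be told from the counts. The tests took the 3 libraries of a group as independent. Libraries of the resubmitted set deviated together from their group means, with a median correlation of 0.718 between groups. RLE scaling moved the median log2 fold change of a clone by at most 0.019. With 10773809 to 18981572 counts per library, a gene at 10 CPM has over 100 counts.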

Results

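The series measured polyadenylated RNA in the haploid laboratory yeast strain BY4742 (Saccharomyces cerevisiae) carrying plasmids with fusion genes, that is, joined parts of different yeast genes. The cells were grown in galactose medium without uracil. The sample labels hold 25 fusion-gene clones and 1 control with the empty GAL1-promoter plasmid, each with 3 biological replicates, so 78 libraries in 26 groups. Replicates 1 and 2 of every group came from a first set of libraries, and replicate 3 came from a resubmitted set, per the library names. Total counts per library ranged from 10773809 to 18981572 with a median of 14019225. The labels do not say which genes were fused in which clone, and the clones are named here by their plate codes. Gene positions are not given, because the count files place genes on contigs of another assembly than the reference used here for gene names.

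The counts on the construct sequences were examined first. The files pool all construct sequences into 1 row, which cannot tell one clone from another. It held 0.412% ± 0.0665 (SD, n = 3) of the counts in the control. It held 2.47% ± 0.36 (SD, n = 3) in M490-F09, 2.27% ± 0.393 (SD, n = 3) in M490-A12 and 2.16% ± 0.218 (SD, n = 3) in M492-C11. In 20 of the 25 clones all 3 libraries lay above all 3 control libraries. M491-E09 overlapped the control at 0.453% ± 0.0589 (SD, n = 3). Below the control lay M491-F10 at 0.281% ± 0.0263 (SD, n = 3), M495-F02 at 0.152% ± 0.00957 (SD, n = 3), M497-F10 at 0.124% ± 0.0424 (SD, n = 3) and M492-E01 at 0.113% ± 0.0268 (SD, n = 3). The files list no construct sequence under the names M497-F10 and M492-E01. The counted stretch was 66 bases for PP2061, the plasmid named for control replicate 3. For clones with a sequence it was 453 (M490-A12) to 2346 bases (M491-E09). The shares were not scaled by this length, and only unique hits were counted, so they do not rank the groups by construct expression. An exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.10, which was the value for each of the 24 clones that did not overlap. The library name of control replicate 3 carries another plasmid name, PP2061, than those of control replicates 1 and 2, while the sample labels give all 3 as the control plasmid. The library names of M492-E01 replicates 1 and 2 carry another plate code, M585-B08, than that of its replicate 3.

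**Figure D1:**
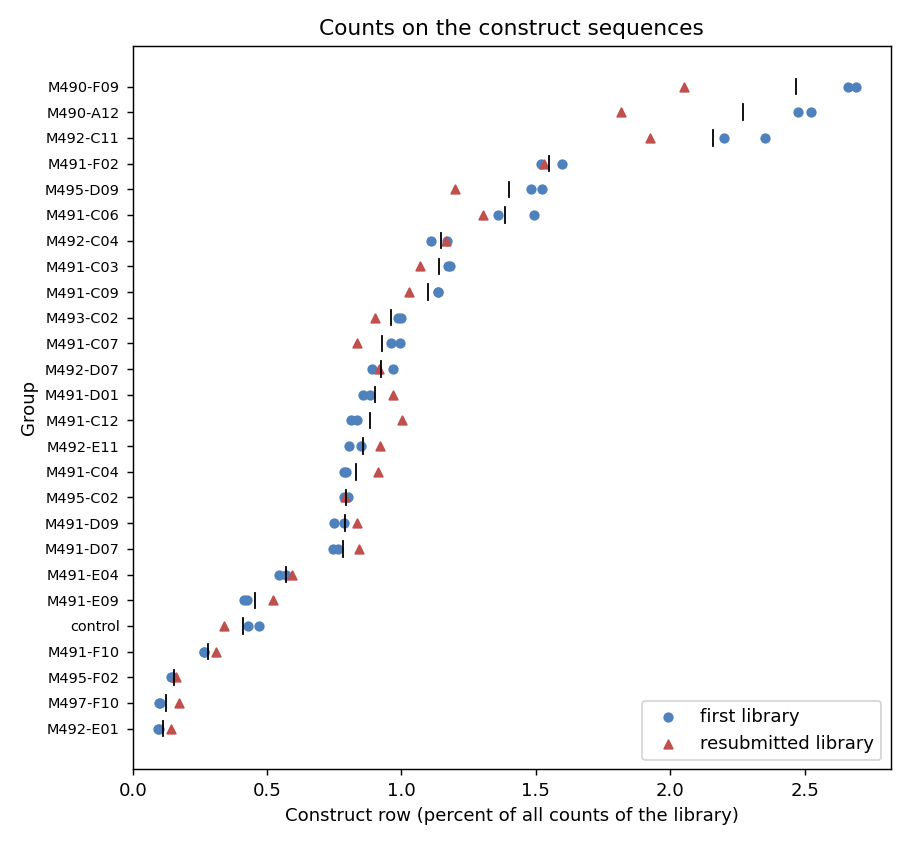
Share of each library's counts on the pooled construct row (x axis, percent of all counts) for the 26 groups (y axis, ordered by mean). Circles are first-set libraries, triangles are resubmitted libraries and vertical bars are group means of 3 libraries. M490-F09 has the highest mean at 2.47%, the control has 0.412%, and 4 clones lie below the control.

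Each clone was then compared with the control to ask which transcripts differed between them. Among 5212 genes tested, M495-F02 had the most changes, with 1330 genes higher and 1285 lower. M491-C07 followed with 634 higher and 620 lower, M490-A12 with 619 higher and 547 lower, and M491-F10 with 598 higher and 464 lower. At the other end M493-C02 had 4 changed genes, M492-C11 had 2 and M492-D07 had 1. The counts also differed by plate row, given by the first letter of the first-set library names. Clones of row A had 672 to 1254 changed genes and those of row B 317 to 684. Those of rows C to E had 1 to 2615. The control was in row E, with M497-F10 as the only clone there. For the other clones an effect of the row cannot be told apart from an effect of the clone. Most changes were small. In M495-F02 170 of the 2615 called genes changed at least 2-fold, and in M490-A12 15 of 1166 did. The counts depended on how the library sets were fitted. Without a term for the set they were 1553 in M495-F02, 451 in M491-C07, 267 in M490-A12 and 321 in M491-F10, and with the first set alone they were 3339, 2512, 1720 and 2065 in the same order. M491-C06, with 1041 genes in the main fit, lay above M490-A12 and M491-F10 in both of these fits, at 383 and 2260. Of the 2615 genes of M495-F02 2463 were also called in the first set alone. At an unadjusted p of 0.05 M493-C02 had 263 genes, M492-C11 had 352 and M492-D07 had 375. Leaving out 1 library gave 1 or 2 genes in M493-C02 for control replicates 2 and 3 and its own replicates 1 and 2, and 2 genes in M492-D07 for control replicate 3. The side with more genes also depended on the fit. With the first set alone M495-F02 had 1663 genes higher and 1676 lower, M490-A12 had 830 and 890, and M491-F10 had 961 and 1104. With RLE in place of TMM scaling the share of higher genes among those called went from 53.6% to 42.4% in M490-F09, from 53.1% to 45.5% in M490-A12, from 50.6% to 48% in M491-C07, from 53.7% to 48.8% in M491-C04 and from 50.4% to 47.4% in M491-C03.

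**Figure D2:**
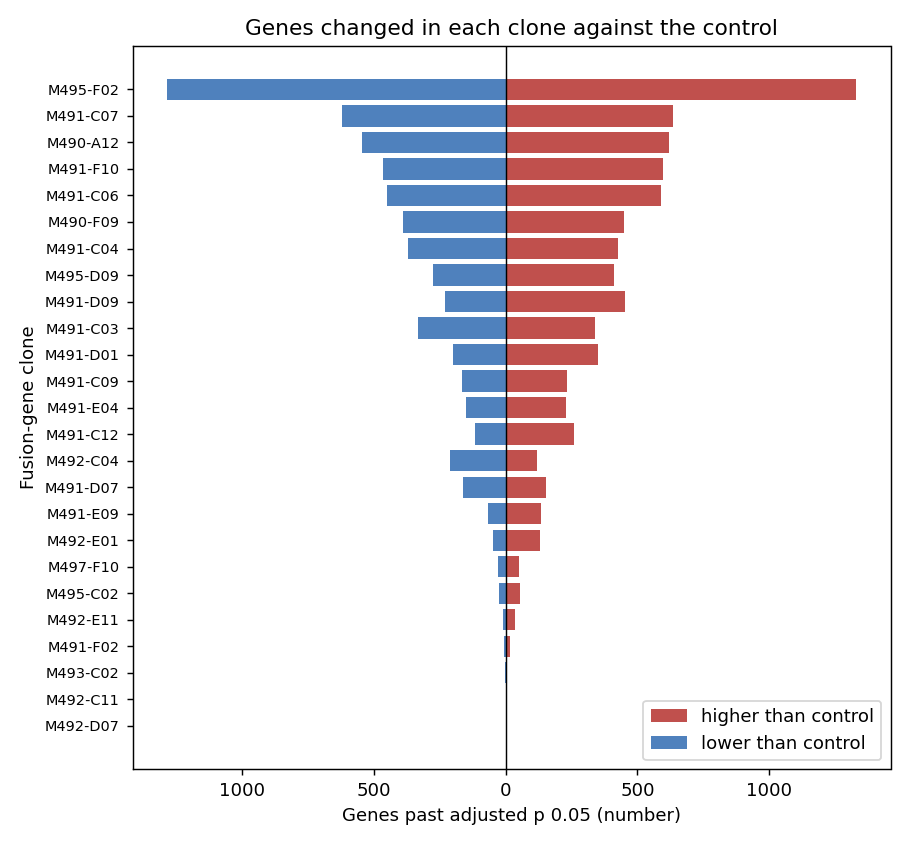
Number of genes past an adjusted p of 0.05 in each clone against the control (edgeR, 3 against 3 libraries in a fit of 78). Bars to the right count genes higher in the clone and bars to the left genes lower. The counts run from 2615 in M495-F02 to 1 in M492-D07.

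In M495-F02 HSP26, BDH2 and HBT1 rose, and FIT2, FET3, CLB1 and genes of galactose use fell. HSP26 (YBR072W), a small heat shock protein, reached 6843 ± 2020 CPM against 1543 ± 77.8 CPM in the control (SD, n = 3 each), a log2 fold change of 2.13 (SE 0.148, adjusted p = 3.3e-18). BDH2 (YAL061W), a putative alcohol dehydrogenase, rose by 2.60 on the log2 scale (SE 0.11, adjusted p = 4.92e-27), HBT1 by 2.88 and YOL014W by 3.21. The iron uptake genes FIT2, FIT3, FET3 and FTR1 fell by 2.17, 2.16, 1.88 and 1.55 on the log2 scale. The cyclin gene CLB1 fell by 1.61 on the log2 scale. Of the 12 genes of the GAL regulon, which takes up and breaks down galactose, 11 fell (12 adjusted over the list alone) and 1 did not pass (camera adjusted p = 1.01e-10, and adjusted p = 0.047 with an estimated correlation). GAL3, PGM2, GAL1 and MTH1 fell by 1.34, 1.21, 1.19 and 1.11 on the log2 scale. HBT1 had a log2 fold change of 3.17 in the first set and 1.78 in the resubmitted library, and YHR022C had 2.34 and 2.40. CLB1 had -2.18 and -0.52, FIT2 -2.45 and -1.41, FIT3 -2.56 and -1.05, FET3 -2.28 and -1.10, and FTR1 -2.02 and -0.64 in the same order.

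M491-F10 shared the direction of several of these genes. HSP12, a membrane-associated stress protein, rose by 1.40 (SE 0.13, adjusted p = 2.11e-12) and HSP26 by 1.64 (SE 0.146, adjusted p = 6.02e-13) on the log2 scale. TKL2, a minor transketolase, rose by 1.38, AHP1, a thiol peroxidase, by 1.08 and GRE2 by 1.24. The kinase gene MRK1 fell by 1.26, the invertase gene SUC2 by 1.11 and FIT3 by 1.64 on the log2 scale. FIT3 had a log2 fold change of -2.01 in the first set and -0.55 in the resubmitted library. Of the GAL regulon 8 of 12 genes fell (8 adjusted over the list alone), among them MTH1 by 0.74 and GAL3 by 0.52 on the log2 scale (camera adjusted p = 1.95e-09, and adjusted p = 0.047 with an estimated correlation). Of 26 general stress genes 14 rose, 3 fell and 9 did not pass (15 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.82e-08), with adjusted p = 0.191 with an estimated correlation. The count of changed genes was 672 without control replicate 1 and 696 without M491-F10 replicate 1, against 1062.

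Proteasome transcripts were raised in M491-C07, as in other clones against the shared control. Of 33 proteasome genes 31 rose and 2 did not pass (31 adjusted over the list alone, camera adjusted p = 4.73e-34, and adjusted p = 0.047 with an estimated correlation). PRE1 rose by 0.54 (SE 0.0579, adjusted p = 6.76e-10), PRE8 by 0.48 and RPN12 by 0.48 on the log2 scale. The joined row SSA4/SSA3, of chaperone genes, rose by 1.21 and CPR6 by 1.13 on the log2 scale. Of 18 heat shock chaperone genes, with CPR6 among them, 15 rose and 3 did not pass (18 adjusted over the list alone, camera adjusted p = 1.79e-13), with adjusted p = 0.219 with an estimated correlation. The acid phosphatase gene PHO3 fell by 1.86, SIT1, a siderophore transporter, by 1.43 and FTR1 by 1.15 on the log2 scale. In the first set and the resubmitted library PHO3 had -2.29 and -0.9, SIT1 -1.74 and -0.58 and FTR1 -1.3 and -0.74. HSP30 rose by 1.07 on the log2 scale, with a log2 fold change of 1.49 in the first set and 0.15 in the resubmitted library. The count of changed genes was 822 without control replicate 1, 826 without M491-C07 replicate 1 and 739 without M491-C07 replicate 2, against 1254.

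In M490-A12 the copper transporter gene CTR1 rose from 66.5 ± 3.16 to 130 ± 2.71 CPM (SD, n = 3 each), a log2 fold change of 0.97 (SE 0.0749, adjusted p = 1.12e-14). ADH4 rose by 1.24, CIT3, a mitochondrial citrate synthase, by 1.17 and BIO2, biotin synthase, by 0.87 on the log2 scale. PHO3, FET3, FTR1 and ERG3 fell by 1.75, 1.41, 1.33 and 0.92 on the log2 scale. Of 76 ribosome biogenesis genes 58 fell and 18 did not pass (67 adjusted over the list alone, camera adjusted p = 1.35e-23), with adjusted p = 0.304 with an estimated correlation. This list also differed between rows of the resubmitted plate, on which M490-A12 was in row A, by -0.55 on the log2 scale. In M490-A12 it was also lower with the first set alone (camera adjusted p = 1.58e-27), where the rows differed by -0.05, and with plate rows as separate batches (adjusted p = 3.52e-23).

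Gene lists were also examined in clones with fewer changes. In M492-E11, with 47 changed genes, 14 of 17 phosphate starvation genes rose and 3 did not pass (15 adjusted over the list alone, camera adjusted p = 4.3e-88, and adjusted p = 7.25e-25 with an estimated correlation). PHO84 (YML123C), the high-affinity phosphate transporter, rose from 53.4 ± 3.64 to 307.9 ± 48.8 CPM (SD, n = 3 each), a log2 fold change of 2.53 (SE 0.0794, adjusted p = 9.36e-34). SPL2 rose by 4.37, the secreted acid phosphatase gene PHO5 by 1.71 and PHM6 by 1.69 on the log2 scale. The count was 26 without control replicate 3 and 27 without M492-E11 replicate 1. In M495-C02 16 of 18 heat shock chaperone genes rose (18 adjusted over the list alone, camera adjusted p = 4.48e-39, and adjusted p = 0.0235 with an estimated correlation), among them BTN2 by 1.14, CPR6 by 0.92 and YDJ1 by 0.83 on the log2 scale. Its count of 79 changed genes was 37, 42 and 133 without control replicates 1, 2 and 3, and 44 and 39 without M495-C02 replicates 1 and 2. In M492-E01 10 of 15 unfolded protein response genes rose (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.78e-16, and adjusted p = 0.000979 with an estimated correlation), with KAR2, the chaperone of the endoplasmic reticulum, up by 0.72 and ERO1 by 0.68 on the log2 scale. Also in M492-E01, 35 of 62 mitochondrial ribosomal protein genes rose (56 adjusted over the list alone, adjusted p = 0.00921 with an estimated correlation). Its count of 177 was 113 and 93 without control replicates 1 and 2, and 72 and 76 without M492-E01 replicates 1 and 2.

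In M490-F09 genes answering to zinc shortage and peroxisomal genes were higher. ADH4 (YGL256W), an alcohol dehydrogenase induced by low zinc, reached 762 ± 128 CPM against 79.4 ± 1.1 CPM (SD, n = 3 each), a log2 fold change of 3.27 (SE 0.17, adjusted p = 1.26e-22). ZPS1 rose by 2.56 and the zinc transporter gene ZRT1 by 1.09 on the log2 scale. Of 11 zinc starvation genes 6 rose, 1 fell and 4 did not pass (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.32e-05), with adjusted p = 0.14 with an estimated correlation. Of 19 peroxisomal genes 10 rose (14 adjusted over the list alone, camera adjusted p = 2.96e-07, and adjusted p = 0.011 with an estimated correlation), with POX1, acyl-CoA oxidase, up by 1.11 and CAT2 by 0.63 on the log2 scale. The count of changed genes was 483 without control replicate 3 and 455 without M490-F09 replicate 3, against 842. In M492-C04 13 of 27 ergosterol genes rose and 1 fell (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.42e-14, and adjusted p = 0.047 with an estimated correlation). ERG3, the sterol C-5 desaturase gene, rose from 848.1 ± 83.4 to 1768 ± 51.1 CPM (SD, n = 3 each), and UPC2, a sterol regulator gene, fell by 0.62 on the log2 scale. In the same clone 4 of 11 DNA damage genes rose (6 adjusted over the list alone, adjusted p = 0.00921 with an estimated correlation), with RNR2 up by 0.86 and DUN1 by 0.73 on the log2 scale.

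In M495-D09 the drug efflux pump gene PDR5 (YOR153W) rose from 505.5 ± 117 to 2236 ± 303 CPM (SD, n = 3 each), a log2 fold change of 2.16 (SE 0.082, adjusted p = 1.94e-29). Of 62 mitochondrial ribosomal protein genes 57 rose (61 adjusted over the list alone, camera adjusted p = 6.02e-47, and adjusted p = 0.00921 with an estimated correlation). Of 18 iron starvation genes 13 fell (14 adjusted over the list alone, camera adjusted p = 8.62e-14, and adjusted p = 0.047 with an estimated correlation), FIT2 by 1.68 and FET3 by 1.38 on the log2 scale. M491-D09 had the same number of iron genes lower, 13 of 18 (14 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation), with FTR1 down by 1.64 on the log2 scale, and 45 of 62 mitochondrial ribosomal protein genes higher (56 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation). FTR1 in M491-D09 had a log2 fold change of -2.1 in the first set and -0.76 in the resubmitted library. In M491-E09 25 of 33 proteasome genes rose (31 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation). In the same clone 4 of 6 genes of the alpha mating type, which is that of BY4742, fell (4 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation), MF(ALPHA)1 by 1.13 and STE3 by 0.74 on the log2 scale. This list was called down in 8 clones, and with an estimated correlation in 1. MF(ALPHA)1 was lower than in the control in 25 of 25 clones. The count of 689 in M495-D09 was 435 without control replicate 1, and 427 and 451 without its replicates 1 and 2. The count of 684 in M491-D09 was 313 without control replicate 1, and 375 and 371 without its replicates 1 and 2, and the count of 203 in M491-E09 was 115 without control replicate 2 and 127 without its replicate 1.

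Leading genes were then sought by comparing each clone with the mean of the other 25 groups, which rests less on the control. In 16 clones at least 1 gene was above every other library and at least 2-fold up. M497-F10 had the largest folds. The files list no construct sequence under its name, so reads of its fusion gene could be counted on genes of the genome. The labels do not name its fused genes. Whether the reads of its leading genes YGR122W and RVB2 came from the fusion or from the genome's own copies cannot be told. YGR122W stood at 5479 ± 126 CPM against 46 ± 5.1 CPM in the control, a log2 fold change of 6.98 against the other groups (SE 0.0243, adjusted p = 2.11e-86), and RVB2 (YPL235W), a helicase subunit of chromatin remodelling complexes, at 10570 ± 819 CPM against 129 ± 11.6 CPM (SD, n = 3 each), a log2 fold change of 6.41. MTG2 led M491-D09 with a log2 fold change of 4.43, YGR035C led M491-C04 with 3.79 and MED6 led M491-D07 with 2.89. CCT6 led M491-F02 with 1.73 and RPL1A/RPL1B, a joined row, led M492-C11 with 1.57. For 6 of the 16 first-ranked leading genes the change between library sets lay outside the range of the other 25 groups. MTG2 had a log2 fold change against the control of 3.06 in the first set and 5.34 in the resubmitted library, MED6 of 1.79 and 3.92, CCT6 of 0.93 and 2.86, YIH1 in M491-E04 of 0.67 and 1.88, ADE4 in M491-C03 of 0.56 and 1.78 and YOL014W in M495-F02 of 3.53 and 2.23. The resubmitted values come from 1 library per group and have no test of their own. M497-F10 had 79 changed genes against the control, 49 without control replicate 2.

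**Figure D3:**
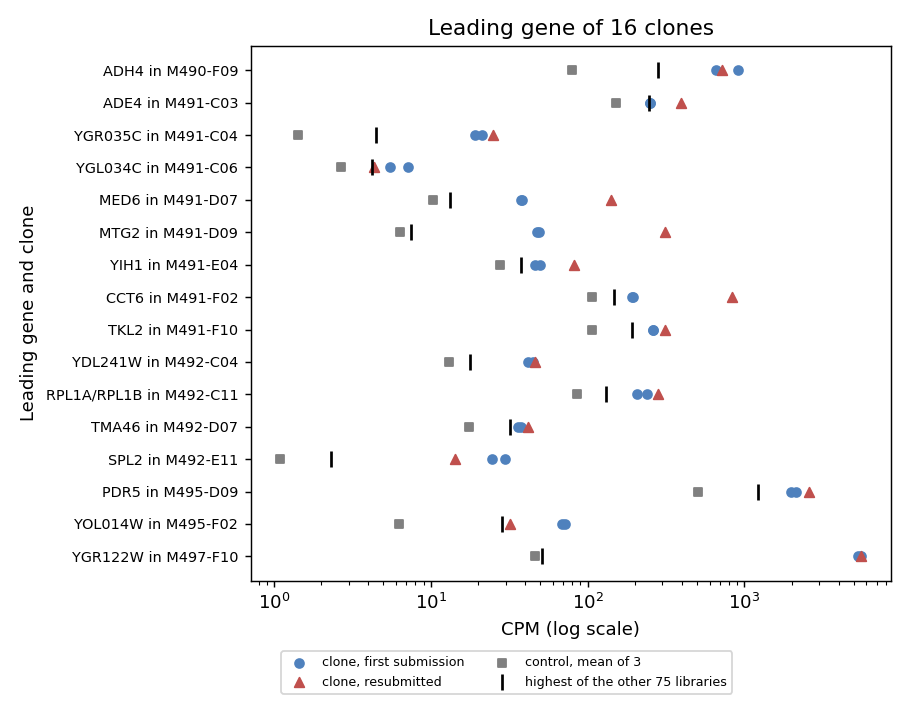
CPM on a log axis (x axis) of the leading gene of each of 16 clones (y axis). Circles are the clone's first-set libraries, triangles its resubmitted library, squares the mean of the 3 control libraries and bars the highest of the other 75 libraries. YGR122W in M497-F10 stands at 5335, 5570 and 5531 CPM, and MTG2 in M491-D09 at 47.9, 49.2 and 311 CPM.

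Several lists were called in the same direction in most clones, all against the same 3 control libraries. The proteasome list was up in 22 of 25 clones, the mitochondrial ribosomal protein list up in 19, the heat shock chaperone list up in 18 and the iron starvation list down in 21, and with an estimated correlation in 2, 3, 1 and 2 clones in the same order. For these lists a call in 1 clone does not set it apart from the others.

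The average of the 25 clones was compared with the control to ask what fusion plasmids shared against the empty plasmid. Past the threshold lay 339 genes, 199 higher and 140 lower. The iron permease gene FTR1 was lower, at 289 CPM over the clones against 478 ± 107 CPM in the control (SD, n = 3), an average log2 fold change of -0.80 (SE 0.125, adjusted p = 5.81e-05), and 23 of 25 clones were lower. FET3 fell by 0.77, INA1 by 1.00 and the joined row ANB1/HYP2 by 0.73 on the log2 scale. Whether that row counts both of its genes cannot be told. AHP1 rose by 0.42 (SE 0.0651, adjusted p = 5.81e-05) and SGT2 by 0.37 on the log2 scale, both in 25 of 25 clones. Of 18 iron starvation genes 10 fell (12 adjusted over the list alone), with adjusted p = 0.139 with an estimated correlation. Of 33 proteasome genes 20 rose (30 adjusted over the list alone), with adjusted p = 0.0933 with an estimated correlation, and of 62 mitochondrial ribosomal protein genes 15 rose (32 adjusted over the list alone), with adjusted p = 0.14 with an estimated correlation. This comparison rests on 3 control libraries, and the count was 98 and 89 without control replicates 1 and 2, 90 and 101 without replicates 1 and 2 of all clones, and 1336 with the first set alone. It was 64 without a term for the library set and 540 with plate rows as separate batches. Of the 30 genes ranked by the fixed rule, 9 passed whichever library or replicate set was left out, and the genes named here by symbol are among these 9. At least 20 of 25 clones lay on 1 side of the control for 41.7% of genes, against 45.8% in simulated libraries with no effect, because all clones share the control.

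Among the 26 groups 4333 of 5212 genes differed, 2381 and 2164 without replicates 1 and 2 of all clones, and 2006 without a term for the library set. Between the library sets 4411 genes differed, 2159 higher and 2252 lower in the resubmitted set. Ribosome biogenesis genes had a median of 0.71 higher on the log2 scale in the resubmitted set (camera adjusted p = 8.04e-18) and cytosolic ribosomal protein genes a median of 0.57 higher (adjusted p = 1.59e-14). Over all 42 lists and 26 contrasts, 404 of 1092 tests passed, 201 up and 203 down, and 18 of them passed with an estimated correlation. The lists of genes of the other mating type and of meiosis, which haploid alpha cells should not use, gave no call in any of the 26 contrasts. Each contrast compared cells of the same strain, so this does not show whether the cells used these genes.

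**Figure D4:**
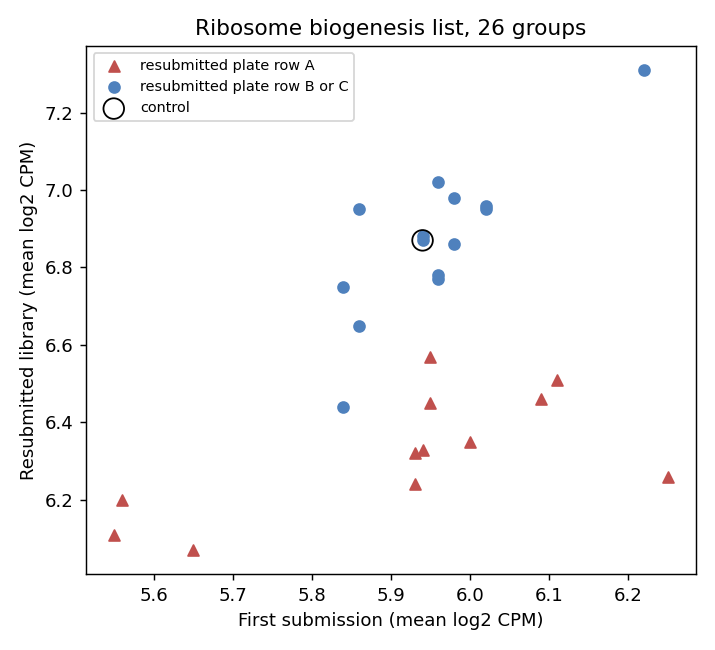
Mean log2 CPM of 76 ribosome biogenesis genes in each of 26 groups, in the first set (x axis, mean of 2 libraries) and in the resubmitted library (y axis). Triangles are the 12 groups in row A of the resubmitted plate, circles the 14 groups in rows B and C, and the ring marks the control. The rows differed by -0.55 in the resubmitted set and by -0.05 in the first set.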

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

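The tests of the plate rows and of the leading genes by library set were chosen after the results were seen, except the test of depth.

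Ribosome biogenesis transcripts differed between rows of the resubmitted plate, and the difference was not the same in the first set. The 12 groups in row A had a mean log2 CPM lower by 0.55 than the 14 groups in rows B and C in the resubmitted set (row A minus rows B and C -0.55, permutation p = 1e-05, the smallest that 100000 resamples can give, two-sided), and -0.05 in the first set (permutation p = 0.481). The change between sets was -0.50 (permutation p = 1e-05). Total counts argue against depth, at 14.7 ± 1.97 M counts in row A and 14 ± 1.65 M counts in rows B and C (SD, permutation p = 0.322). A batch within the resubmitted plate is a candidate explanation, and whether it arose in growth or in library preparation stays open. No biological explanation was tested, since plate rows are no group of the design.

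The leading genes of 9 clones passed an interaction test between clone and library set (edgeR, Benjamini-Hochberg over 16 genes). The resubmitted side of each group is 1 library, so the error of this test comes from the first-set pairs alone, which lie closer together than libraries of different sets, and the test alone does not show that the folds differ. Against the other groups, the log2 change from the first set to the resubmitted library was 2.62 for MTG2 in M491-D09, 2.11 for MED6 in M491-D07, 1.88 for CCT6 in M491-F02, 1.20 for YIH1 in M491-E04, 0.94 for ADE4 in M491-C03, 0.59 for YGR035C in M491-C04, -0.38 for ADH4 in M490-F09, -0.43 for TMA46 in M492-D07 and -1.22 for YOL014W in M495-F02. Set against the other 25 groups, 6 of the 9 moved between sets beyond all of them (MTG2, MED6, CCT6, YIH1, ADE4 and YOL014W). ADE4 did so narrowly, at 0.67 against up to 0.57. For a gene picked without regard to its levels chance gives 7.69%. The 16 leading genes were chosen for high levels in their clone in the same libraries, and the 9 for their change between sets. That share is therefore no measure of chance for them, and the count cannot decide on a batch effect on the gene itself. The other 3, ADH4, YGR035C and TMA46, moved by -0.11, 0.31 and 0.19, inside the range of the other groups, so for them such a batch effect stays open as well. Reads of the construct that are assigned to the gene in unequal shares may be a source for genes that are parts of a fusion. The construct share moved against the gene beyond all other clones in 0 of the 9 clones, but the needed move was at most 0.06 on the log2 scale against an SD of 0.239 between other clones, so the test cannot decide. The clone's own biology in another culture stays open and untested.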

How the results depend on the processing

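The alternative with rows of the resubmitted plate was chosen after seeing the data, and the others before. RLE size factors and no filter on low counts kept every count within 1.5 times, and the leading genes of 16 clones kept their direction and call under every alternative that gave a value. DESeq2 gave no adjusted p for 3 of these leading genes, YGR035C, RPL1A/RPL1B and TMA46, so they have no call there. Their DESeq2 log2 fold changes against the other groups were 3.8, 1.57 and 1.27 in the same order. A replicate block in place of the library set term moved no count by over 1.5 times and gave 324 genes for the average of the clones and 4309 among the groups. The difference between replicates 1 and 2 had a median correlation of 0.0128 between groups, with a lowest of -0.307. The median gives no common direction by replicate number over the groups. It cannot show whether libraries of some groups shared handling. ADE17 in M491-C07 and FAA4 in the average lost their call with the block. DESeq2 gave 35 for M491-F02 and 119 for M495-C02. An estimated correlation left 18 list tests of 404. The other fits were followed for 38 list results, those called in the average of the clones or with an estimated correlation. Of these 3 lost their call without a term for the library set, 4 with the first set alone and 3 with plate rows as separate batches. Over the fits without a replicate number of all clones a call was lost 5 times, and over those without a control library 16 times. Without a term for the library set the edgeR numbers of called genes were 267 for M490-A12, 138 for M490-F09, 147 for M491-C03, 131 for M491-C04, 383 for M491-C06, 451 for M491-C07, 47 for M491-C09, 48 for M491-C12, 115 for M491-D01, 27 for M491-D07, 121 for M491-D09, 51 for M491-E04, 31 for M491-E09, 1 for M491-F02, 321 for M491-F10, 110 for M492-C04, 1 for M492-C11, 0 for M492-D07, 38 for M492-E01, 18 for M492-E11, 0 for M493-C02, 26 for M495-C02, 242 for M495-D09, 1553 for M495-F02, 24 for M497-F10, 64 for the average of the clones and 2006 for the comparison among groups. There the spread between the sets counts as error. With the first set alone they were 1535 for M490-F09, 1433 for M491-C03, 1627 for M491-C04, 2260 for M491-C06, 2512 for M491-C07, 1191 for M491-C09, 1243 for M491-C12, 1459 for M491-D01, 1686 for M491-D07, 1812 for M491-D09, 1284 for M491-E04, 848 for M491-E09, 533 for M491-F02, 2065 for M491-F10, 744 for M492-C04, 380 for M492-C11, 602 for M492-D07, 769 for M492-E01, 160 for M492-E11, 74 for M493-C02, 910 for M495-C02, 1693 for M495-D09, 329 for M497-F10 and 1336 for the average of the clones. There the fit has fewer libraries and no resubmitted ones, and why counts rose was not tested. With plate rows as separate batches they were 919 for M491-D01, 801 for M491-D07, 624 for M491-E04, 398 for M491-E09, 74 for M491-F02, 197 for M495-C02, 125 for M497-F10 and 540 for the average of the clones, and the cause was not tested. Leaving out 1 library (or, for the average, groups and lists, 1 replicate number of all clones) gave 382 to 483 for the list tests, 802 to 1025 for M490-A12, 455 to 717 for M490-F09, 426 to 554 for M491-C03, 544 to 649 for M491-C04, 656 to 1136 for M491-C06, 739 to 1415 for M491-C07, 157 to 367 for M491-C09, 133 to 340 for M491-C12, 250 to 548 for M491-D01, 96 to 425 for M491-D07, 313 to 584 for M491-D09, 191 to 375 for M491-E04, 115 to 169 for M491-E09, 7 to 24 for M491-F02, 672 to 982 for M491-F10, 231 to 266 for M492-C04, 2 to 3 for M492-C11, 1 to 2 for M492-D07, 72 to 177 for M492-E01, 26 to 44 for M492-E11, 1 to 3 for M493-C02, 37 to 133 for M495-C02, 427 to 708 for M495-D09, 2230 to 2695 for M495-F02, 49 to 81 for M497-F10, 89 to 1336 for the average of the clones, 2164 to 4814 for the comparison among groups and 4387 to 4409 for the library sets. Each of these fits has fewer libraries, and where a count rose the cause was not tested. Of 157 pairs of a named gene and a clone against the control, 135 stayed past the threshold without any 1 library. Of 199 results on named genes 51 lost their call without a term for the library set. No named gene reversed its direction in the fits above. The ribosome biogenesis list in M491-C03 did reverse, from lower (camera adjusted p = 0.045) to higher with the first set alone (adjusted p = 0.0327), and was higher with plate rows as separate batches (adjusted p = 0.23), and the cause was not tested. DESeq2 moved 2 counts by over 1.5 times, and the cause was not tested. Depth limits the genes with the fewest counts, of which 17 were not tested.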

Other observations

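The tests that set other clones in the control's place or fitted plate rows were chosen after the result was seen. Further genes changed in some clones. In M491-C03 ADE4, the first enzyme of purine synthesis, rose by 1.02 on the log2 scale against the control (SE 0.208, adjusted p = 0.000514), with 2 of 16 purine genes past the threshold (4 adjusted over the list alone) and adjusted p = 0.713 with an estimated correlation for the list. The peroxisomal list was called up in 13 clones, in 3 of them also with an estimated correlation. In M491-C09 7 of 19 peroxisomal genes rose (8 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation), CAT2 by 0.56 on the log2 scale. In M491-E09 4 of the same 19 rose (5 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation), FOX2 by 0.35 on the log2 scale. In M492-C04 the cell wall gene HPF1 rose by 1.75 and CLB1 fell by 1.59 on the log2 scale. MCD4, a gene of anchor synthesis in the endoplasmic reticulum, rose by 0.85 on the log2 scale in M492-E01. These values belong to clones whose fusion partners the labels do not name.

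The difference of the control from the mean of the clones was 339 genes. Put in the control's place, 17 of the 25 clones gave as many called genes or more against the mean of the other groups, so a difference of this size may be what any 1 group shows, and a response shared by all fusion plasmids is not needed for it. With row A of the resubmitted plate fitted apart from rows B and C the count was 540. That fit kept row C, which held the control and M497-F10, together with row B. It therefore cannot decide whether plate rows are a source of the difference. Whether fusion plasmids share a response against the empty plasmid stays open, with 3 control libraries.

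Other groupings of the same libraries were counted as planned. For the differences among groups 1 of 100 groupings within library sets, the real one, gave 4333 genes and the highest other gave 158. The other groupings break up the pairs of replicates 1 and 2, which lie close together. A random mix of the libraries thus does not give the real count. The test cannot tell an effect of the clone from what the 2 libraries of a pair shared. For the average of the clones the real grouping gave 339, the highest other 122 and 1 of 100 reached the real count. These groupings mix libraries of clones that differ, which adds to the error, so they do not set the control apart, and with groups kept whole 17 clones reached 339 as given above. For the library sets 1 of 100 reached the real 4411 genes and the highest other gave 1976. For the list tests 4 of 100 groupings gave as many as the real 404 calls and the highest other gave more than the real count, so that their share is under 0.05 but the number of calls alone does not set the real grouping apart. Camera with a preset correlation thus calls many lists under regrouped labels, which points to genes of a list that move together between libraries. For single clones the 10 splits of 6 libraries are too few for a share under 0.05. The real count and the highest of the other splits were 1166 and 3 in M490-A12, 842 and 0 in M490-F09, 672 and 1 in M491-C03, 797 and 49 in M491-C04, 1041 and 601 in M491-C06, 1254 and 1009 in M491-C07, 401 and 0 in M491-C09, 375 and 0 in M491-C12, 550 and 0 in M491-D01, 317 and 13 in M491-D07, 684 and 94 in M491-D09, 381 and 38 in M491-E04, 203 and 3 in M491-E09, 23 and 1 in M491-F02, 1062 and 21 in M491-F10, 332 and 6 in M492-C04, 2 and 0 in M492-C11, 177 and 14 in M492-E01, 47 and 1 in M492-E11, 4 and 0 in M493-C02, 79 and 2 in M495-C02, 689 and 127 in M495-D09, 2615 and 1229 in M495-F02. There 1 of the 10 splits, the real one, reached the real count. In M497-F10 3 of 10 splits reached 79 genes and the highest other gave 186, and in M492-D07 3 of 10 reached 1 and the highest other gave 1. The high other counts of M495-F02, M491-C07 and M491-C06 came from the split that swaps the resubmitted libraries of clone and control, which leaves the first-set libraries in their own groups.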
